A study of Mus musculus with 21 samples.

How the data were processed

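Gene expression was measured in 21 mouse tumours on Clariom S mouse arrays, 1 array per mouse, in 4 arms of 6, 5, 5 and 5 mice. The deposited values are log2 signals, made by the authors with RMA and the oligo package per the submitters' processing notes, with no versions named, and their scale was checked on the values. RMA corrects the background, quantile-normalizes the arrays and summarizes probes to a probe set, so levels are relative within the set of arrays and a change shared by most genes is removed. The genome build and annotation behind the arrays are not given in the sources used here. Each mouse was placed in its arm from its treatment label. The mice are separate animals, so p-values measure the spread between mice.

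The table held 29129 rows, of which 6923 control rows were left out and 22206 probe sets were tested. Gene names came from the array platform's annotation, with symbols updated through the gene identifiers: 19572 probe sets had 1 symbol, 0 had several and 2634 are unnamed here. They stand for 19505 genes, of which 55 had over 1 probe set. For gene lists the probe set with the highest mean over all mice stood for a gene. The 5222 negative-control rows had a median of 4.10, and 5174 tested probe sets had a mean below it in each of the 4 arms. No filter on dim probe sets was applied. The arrays have no read depth, and their number limits the precision.

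The fit was limma (version 3.58.1, with statmod 1.5.0, in R 4.3.3), with lmFit and eBayes on 4 group means over all 21 arrays and 7 contrasts: the 6 pairs of arms and the interaction. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, two-sided. Gene lists were tested with fry from limma by its one-way p, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, adjusted over the 39 lists within a contrast. The lists held 616 genes, of which 564 were measured and 52 were not matched to a named probe set, and a list needed at least 3 measured members. Lists share some genes, such as Eomes and Klrd1 in the cytotoxic and NK cell lists. The standard error and 95% interval of a list are those of the difference in its mean score. The mean and the median of the members' differences had opposite signs for 1, 3, 2, 3, 1 and 2 lists in the pairs lenvatinib, anti-PD1 and combination against placebo, combination against lenvatinib and against anti-PD1, and lenvatinib against anti-PD1, and for 1 in the interaction.

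The groups, tests, lists, alternatives other than those said to be later, and the rule for naming genes were fixed before the data were examined. The rule takes, for each comparison, up to 10 genes in each direction with the largest change among those past the threshold, or, where none passed, the 3 with the smallest p in each direction, leaving out provisional names. It adds the 4 members with the smallest p of each list that passed and up to 2 of each list that did not, and the receptors that lenvatinib inhibits with Pdcd1 and Cd274. Pdgfra is among the genes unnamed here.

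The alternatives were a filter at the 40th percentile of mean signal, eBayes with trend and robust settings, cyclic loess normalization, array weights, a fit of only the 2 groups compared, the mouse number as a block, a 1.5-fold threshold, an adjusted p under 0.1, camera with a preset correlation of 0.01 and with an estimated correlation, an exact two-sided permutation test of list scores, and leaving out each mouse in turn. Added after the data were seen were the hybridization control signal as a covariate, leaving out the 6 arrays with bright controls, leaving out combination mice 3 and 4, and array weights for lists. Other splits of the mice were drawn 100 times per comparison.

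The fit was tested on simulated data, made by shuffling residuals among mice around each probe set's mean, in 20 draws with 200 of 22206 probe sets changed. For the combination against anti-PD1 it recovered 41.4% of 2-fold, 86.6% of 4-fold and 97.3% of 8-fold changes, all with the right sign. False calls had a median of 0.5, in 10 of 20 draws, with 1689 in the highest. For lenvatinib against placebo it recovered 46.2%, 90.5% and 97.7% at the same folds, with a median of 0 false calls and 17 in the highest draw. A T cell list shifted by 1 and 1.5 log2 was called in 9 and 15 of 20 draws for the combination against anti-PD1, and in 4 and 19 for lenvatinib against placebo. With no shift it was called in 0 of 20 draws in both, and any other list was called in at most 2.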

Results

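The data are gene expression profiles of 21 tumours, each from a different mouse. The tumours arose from Hepa1-6 cells, a mouse hepatoma line, injected under the skin of female C57BL/6J mice. Mice entered 1 of 4 arms at random when their tumours measured 200 mm3. Of these, 6 received vehicle with a polyclonal IgG (placebo), 5 received lenvatinib, 5 received an antibody against the PD-1 receptor (anti-PD1), and 5 received both agents (combination). Lenvatinib inhibits the VEGF and FGF receptors and a few related kinases, and was given by mouth at 10 mg/kg every day. PD-1 is an inhibitory receptor of T cells, and the antibody was injected at 10 mg/kg every 3 days for 5 doses. Tumours were taken on day 13, 2 h after the last lenvatinib dose and 1 day after the last antibody dose, and RNA from 30 mg of tissue was run on Clariom S mouse arrays. Values are log2 signals, and differences between arms are given as the log2 difference ± its standard error. A list score is the mean over a gene list after each gene was centred on its mean over the 21 mice. The 4 arms form a factorial design, which asks what each agent did alone, what the combination did beyond each agent, and whether the effects add up on the log2 scale.

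Array medians lay between 5.33 and 5.49 over the 22206 probe sets tested, and the number of arrays limits the precision of every comparison. Genes of other tissues differed widely between the tumour pieces. Skeletal muscle genes, such as those of the fast contractile fibres, had list scores of 3.77 and 3.69 in placebo mice 1 and 5. Scores were 3.47 in lenvatinib mouse 4, 3.04 in anti-PD1 mouse 2 and 4.52 in combination mouse 2, against -1.70 in anti-PD1 mouse 4. Adipocyte scores ran from -2.61 in combination mouse 1 to 2.93 in anti-PD1 mouse 2. Their arm means were 0.80 ± 1.68 (SD, n = 6) in placebo, -1.38 ± 1.06 (SD, n = 5) in lenvatinib, 0.72 ± 2.34 (SD, n = 5) in anti-PD1 and -0.30 ± 1.44 (SD, n = 5) in the combination. Mitotic genes, which mark dividing cells, ran from -1.63 in anti-PD1 mouse 2 to 1.38 in anti-PD1 mouse 5. The hybridization controls, bacterial transcripts added just before hybridization, averaged 10.9 or more on 6 arrays and 10.4 or less on the other 15. These 6 arrays were placebo mice 4 and 6, lenvatinib mice 1 and 2, anti-PD1 mouse 1 and combination mouse 1. Their signals spread less, with interquartile ranges of 2.41 to 2.82 against 3.00 to 3.25 on the others. The first principal component held 29.2% of the variance, and the second, along which those 6 arrays lay apart, held 24.1%.

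**Figure D1:**
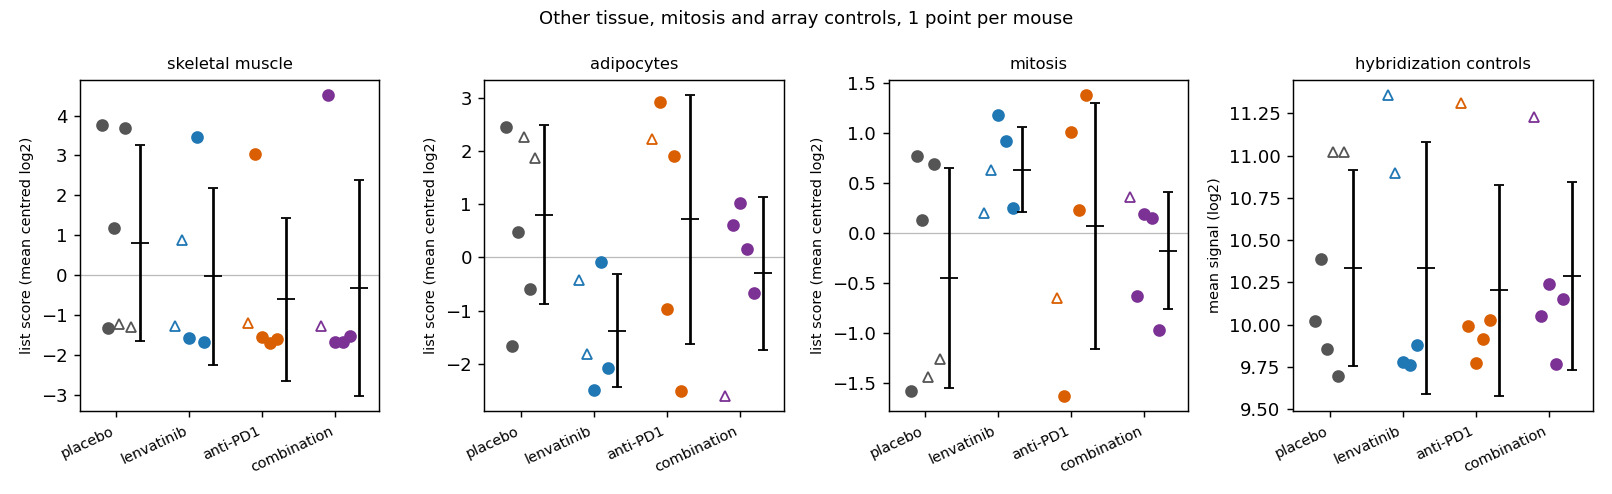
Scores of the skeletal muscle, adipocyte and mitosis lists (mean centred log2) and the mean log2 signal of the hybridization controls, 1 point per mouse, by arm, with open triangles for the 6 arrays with bright controls and black bars for the arm mean ± SD (n = 6, 5, 5 and 5). Muscle scores lie above 3 in 5 mice, and the 6 triangles in the control panel lie at 10.9 or above.

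What lenvatinib did alone was read from 5 lenvatinib and 6 placebo tumours. No gene list passed its test, and the lists with the smallest p-values concerned stroma, signalling below growth factor receptors and the tumour cells. Fibroblast and matrix genes stood at -0.91 ± 0.38 (fry adjusted p = 0.387), with 15 of 16 members below 0 and 5 of 5 lenvatinib tumours below the placebo mean. Among them were Mfap5, a microfibril protein, at -1.53 ± 0.43 and Loxl1, an enzyme that cross-links elastin, at -1.19 ± 0.42. Transcripts driven by MAP kinase and FGF receptor signalling stood at 0.59 ± 0.27 (adjusted p = 0.387), with 15 of 17 above 0 and 5 of 5 tumours above the placebo mean. Of these, the feedback inhibitor Spred1 stood at 0.72 ± 0.21 and the transcription factor Etv4 at 1.27 ± 0.52. Hepatocyte lineage genes, expressed by the tumour cells, stood at 0.88 ± 0.40, with Ttr, a thyroid hormone carrier, at 2.15 ± 0.79 and the clotting factor gene F2 at 1.70 ± 0.58. The Wnt target Nkd1 stood at 2.17 ± 0.82. All 20 mitosis genes lay above 0, at 1.08 ± 0.55 as a list, with Ube2c, which helps to end mitosis, at 1.60 ± 0.61. All 11 adipocyte genes lay below 0, at -2.17 ± 1.02, with the hormone gene Retn at -3.64 ± 1.35 and the lipogenic gene Thrsp at -3.98 ± 1.35. Placebo mice 1, 4 and 6, with adipocyte scores of 2.44, 2.27 and 1.87, had mitosis scores of -1.57, -1.44 and -1.255. Placebo mice 2, 3 and 5 stood at 0.77, 0.13 and 0.70, against a lenvatinib mean of 0.64. Mice 1, 4 and 6 also had the lowest MAP kinase, hepatocyte lineage and Wnt target scores of the placebo arm. These lists are thus not separate readings, and whether tissue make-up lies behind them was not tested.

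Endothelial genes did not separate lenvatinib from placebo tumours. Pericyte and vascular smooth muscle scores averaged -0.17 ± 0.15 (SD, n = 5) in lenvatinib and 0.17 ± 0.31 (SD, n = 6) in placebo. In that list 5 of 5 lenvatinib tumours lay below the placebo mean and 2 below every placebo tumour, without passing the test. The endothelial list stood at -0.29 ± 0.33 with a 95% interval of -0.98 to 0.41, with Nos3, the endothelial nitric oxide synthase, at -0.61 ± 0.23 and the tight junction gene Cldn5 at -1.68 ± 0.71. Among the receptors that lenvatinib inhibits, Kdr stood at -0.48 ± 0.62, Flt1 at 0.27 ± 0.41 and Flt4 at 0.46 ± 0.30. Fgfr1 stood at -0.61 ± 0.34, Fgfr2 at -0.68 ± 0.56, Fgfr3 at -0.07 ± 0.18, Fgfr4 at 1.44 ± 0.66, Kit at -0.99 ± 0.81 and Ret at 0.40 ± 0.16. Without placebo mouse 1 the endothelial list stood at -0.10 and Kdr at -0.14, and without lenvatinib mouse 1 Kit stood at -0.50. Without lenvatinib mouse 5, Flt1 stood at -0.03 and Fgfr3 at 0.00. Hypoxia genes stood at 0.32 ± 0.23 (0.18 without placebo mouse 6), with the glycolytic gene Pgk1 at 0.91 ± 0.34. Interferon-gamma response genes stood at 0.55 ± 0.32, 20 of 21 of them above 0, and Cd274, the gene of PD-L1, stood at 0.65 ± 0.39. Placebo mice 1, 4 and 6 lay low in that list, at -0.87, -0.83 and -0.79, against 0.48, 0.58 and 0.47 in placebo mice 2, 3 and 5. Macrophage, T cell, NK cell, dendritic cell and neutrophil lists each had 4 of 5 lenvatinib tumours below every placebo tumour, with lenvatinib mouse 5 the exception. B and plasma cell lists had 1 and 0 such tumours. The single genes with the smallest p-values on the higher side were Pzp, a protease inhibitor of plasma, at 1.21 ± 0.25, Adam3 at 1.06 ± 0.24 and the actin regulator Wasf1 at 0.86 ± 0.20, all with a placebo mean below the median of the negative controls. On the lower side were Lcn2, an iron-siderophore carrier of neutrophils and epithelia, at -3.45 ± 0.78, the BMP regulator Bmper at -1.23 ± 0.31 and Fcrls at -1.20 ± 0.31. With limma 0 of 22206 probe sets passed (smallest adjusted p = 0.694), and 0 passed with array weights. At an unadjusted p under 0.05, 649 were higher and 899 lower, where chance gives 1110 in all. Of the 39 lists, fry called 0, with 3 at an unadjusted p under 0.05, camera with a preset correlation called 11, and camera with an estimated correlation and an exact permutation test called 0.

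Anti-PD1 alone was set against placebo in 5 and 6 tumours. Lists of immune cells lay below placebo, without passing the test over all lists. Macrophage and monocyte genes stood at -1.13 ± 0.37, a ratio of 0.457 (fry adjusted p = 0.126), and 5 of 5 anti-PD1 tumours lay below the placebo mean. All 16 members lay below 0, and 14 were past the threshold adjusted over the list alone, against 0 over all genes. They include Tyrobp, a signalling adaptor of myeloid cells, at -1.50 ± 0.41 and Ms4a7 at -1.45 ± 0.42. T cell genes stood at -0.91 ± 0.33 (adjusted p = 0.221), with all 13 below 0 and 7 past the threshold adjusted over the list alone. Of these, the T cell receptor chains Cd3g and Cd3d stood at -2.03 ± 0.54 and -1.76 ± 0.55. The T cell scores of 5 of 5 anti-PD1 tumours lay below those of all placebo tumours, with anti-PD1 mouse 4 and placebo mouse 2 nearest, both at -0.18. This gave an exact two-sided permutation p of 0.00216, the smallest possible here, and adjusted p = 0.0844 over the 39 lists. A single list at that smallest p cannot pass after adjustment. Over its 20 alternatives the list had adjusted p = 1.28e-12 to 0.39. It passed in 1 of them, camera with a preset correlation. Cytotoxic lymphocyte genes stood at -0.72 ± 0.31, with 5 of 18 past the threshold adjusted over the list alone, including Cd8b1, a chain of the CD8 co-receptor, at -1.58 ± 0.52 and Cst7 at -1.37 ± 0.40. Pdcd1, which encodes the receptor that the antibody binds, stood at -1.12 ± 0.50 and its ligand gene Cd274 at -0.55 ± 0.39. The lectin Clec4d, listed with neutrophil genes, stood at -2.82 ± 0.62, and Trem2, a lipid receptor of macrophages, at -2.08 ± 0.58. Without anti-PD1 mouse 2, rich in muscle and adipocyte genes, the cytotoxic list stood at -0.47, Cd3d at -1.05, Cd8b1 at -1.02, Pdcd1 at -0.71 and Cd274 at -0.13. The T cell list then stood at -0.69 and the macrophage list at -0.96.

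Above placebo in that comparison lay the erythroid list at 0.30 ± 0.08 (fry adjusted p = 0.126), with 2 of 6 past the threshold adjusted over the list alone. Cholesterol synthesis genes stood at 0.39 ± 0.17, 14 of 15 above 0, with Hmgcs1, which makes the precursor of mevalonate, at 1.21 ± 0.35. By single gene, the transcription factor Mecom stood at 1.15 ± 0.29, the scaffold protein Dlg5 at 0.76 ± 0.20 and Wasf1 at 0.91 ± 0.20. The protease gene Adam8 stood at -2.27 ± 0.51 and Zmynd15 at -0.93 ± 0.21. In limma 0 of 22206 probe sets passed (smallest adjusted p = 0.82), and 0 passed with array weights. At an unadjusted p under 0.05, 307 were higher and 596 lower, against 1110 by chance. Of the 39 lists, fry called 0, with 8 at an unadjusted p under 0.05, camera with a preset correlation called 24, and camera with an estimated correlation called 0. Without anti-PD1 mouse 4 the macrophage list passed, at -1.41 (fry adjusted p = 0.0287). It passed in 2 of its 20 alternatives (adjusted p = 2.78e-21 to 0.377), the other being camera with a preset correlation. The erythroid list passed without placebo mouse 5 (adjusted p = 0.0447), without anti-PD1 mouse 2 (adjusted p = 0.0411) and after cyclic loess normalization (adjusted p = 0.0441). It passed in 4 of its 19 alternatives (adjusted p = 0.00274 to 0.332), the other being camera with a preset correlation.

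Both agents together were set against placebo in 5 and 6 tumours. Lymphocyte lists lay above placebo, and no list passed. B cell genes stood at 1.08 ± 0.50 (fry adjusted p = 0.499), with 5 of 12 past the threshold adjusted over the list alone and 0 over all genes. Among them Cd79a, a chain of the B cell receptor complex, stood at 1.79 ± 0.56 and the kinase Blk at 0.98 ± 0.35. That list had scores of 3.45 and 1.36 in combination mice 4 and 3, and at most 0.32 in the other 19 tumours. T cell genes stood at 0.62 ± 0.33 (adjusted p = 0.499), with all 13 above 0 and 3 past the threshold adjusted over the list alone. Cd247, the zeta chain of the T cell receptor, stood at 0.80 ± 0.24 and the adaptor Sit1 at 1.09 ± 0.38. Dendritic cell genes stood at 0.33 ± 0.17, 10 of 13 above 0. Without combination mouse 4 the B cell list stood at 0.43, Cd79a at 1.07, Blk at 0.48, the T cell list at 0.38 and the dendritic cell list at 0.18. Below placebo lay the Schwann cell list at -0.44 ± 0.16 (adjusted p = 0.406), with 1 of 6 past the threshold adjusted over the list alone and the myelin gene Mbp at -0.84 ± 0.27. Pericyte and vascular smooth muscle genes stood at -0.32 ± 0.21 (-0.18 without combination mouse 1), with the proteoglycan Cspg4 at -0.66 ± 0.25 and the actin-binding protein Tagln at -0.74 ± 0.32. The basal keratin Krt14 stood at -1.85 ± 0.59. Endothelial genes stood at -0.04 ± 0.33, and from -0.17 without combination mouse 4 to 0.14 without placebo mouse 1.

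The single genes with the smallest p-values for the combination against placebo were Adtrp at -2.20 ± 0.41, Reep6 at -1.62 ± 0.37 and Vnn1 at -1.33 ± 0.31 on the lower side. On the higher side were Camk4, a calcium-dependent kinase, at 0.92 ± 0.21, B3gnt5 at 1.69 ± 0.44 (1.10 without combination mouse 4) and Fam102a at 0.90 ± 0.24. With limma 0 of 22206 probe sets passed (smallest adjusted p = 0.602), and 0 passed with array weights. At an unadjusted p under 0.05, 224 were higher and 288 lower, against 1110 by chance. Of the 39 lists, fry called 0, with 2 at an unadjusted p under 0.05, camera with a preset correlation called 20, and camera with an estimated correlation and an exact permutation test called 0.

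What anti-PD1 added to lenvatinib was read from 5 combination and 5 lenvatinib tumours. All 13 T cell genes lay above lenvatinib alone, at 1.08 ± 0.34 as a list, a ratio of 2.12, although the list did not pass among all 39 (fry adjusted p = 0.169). Of these genes 9 were past the threshold adjusted over the list alone, and 0 over all genes. Cd2, an adhesion receptor of T cells, stood at 1.42 ± 0.32 and Cd247 at 1.00 ± 0.25. The CD8 chains Cd8a and Cd8b1 stood at 1.54 ± 0.53 and 1.55 ± 0.54. Dendritic cell genes stood at 0.49 ± 0.18 (adjusted p = 0.245), all 13 above 0, with the growth factor receptor Flt3 at 0.79 ± 0.28 and Siglech, a marker of plasmacytoid cells, at 1.17 ± 0.45 (0.56 without combination mouse 4). Combination mice 3 and 4, high in B cell genes, had dendritic cell scores of 0.45 and 0.96, against -0.15, 0.06 and 0.55 in mice 1, 2 and 5. Their T cell scores were 0.61 and 1.78, against -0.41, 0.90 and 1.13. All 16 macrophage genes lay above 0 too, at 0.83 ± 0.38, with Csf1r, the receptor for the macrophage growth factor, at 0.95 ± 0.36 and Adgre1, the F4/80 antigen, at 1.34 ± 0.52. Interferon-gamma response scores went the other way, averaging 0.39 ± 0.26 in lenvatinib and 0.08 ± 0.22 in the combination (SD, n = 5 and 5). In that list 4 of 5 combination tumours lay below every lenvatinib tumour, without passing the test. Hepatocyte lineage genes stood at -0.82 ± 0.42, 21 of 23 below 0, with the retinol carrier Rbp4 at -1.10 ± 0.36 (-0.72 without combination mouse 5). All 20 mitosis genes lay below 0, at -0.81 ± 0.58. Fibroblast and matrix scores averaged -0.54 ± 0.55 in lenvatinib and 0.12 ± 0.56 in the combination (SD, n = 5 and 5), and pericyte scores -0.17 and -0.16. Whether the share of tumour cells differed was not tested in this comparison. Other genes with the smallest p-values were Rassf5, an effector of lymphocyte adhesion, at 1.28 ± 0.30, the phosphatase Dusp2 at 0.85 ± 0.20, Adam3 at -1.13 ± 0.25, Slc44a3 at -1.27 ± 0.34 and Nav3 at -1.14 ± 0.31.

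In limma 0 of 22206 probe sets passed for the combination against lenvatinib (smallest adjusted p = 0.78). At an unadjusted p under 0.05, 860 were higher and 561 lower, against 1110 by chance. Of the 39 lists, fry called 0, with 6 at an unadjusted p under 0.05, camera with a preset correlation called 24, and camera with an estimated correlation and an exact permutation test called 0. Array weights, which gave lenvatinib mice 3 and 4 weights of 2.49 and 3.63, called 346 probe sets higher and 361 lower. With these weights the T cell list (adjusted p = 0.00706), the dendritic cell list and the hepatocyte lineage list (both at adjusted p = 0.0203) passed. The T cell list passed without lenvatinib mouse 5 (adjusted p = 0.0495), whose T cell score of 0.54 lay above those of the other 4 lenvatinib mice. Without combination mouse 1 the T cell list (adjusted p = 0.0068), the dendritic cell list (adjusted p = 0.0269) and 1 probe set passed. Over 20 alternatives each, the adjusted p ran over 2.12e-14 to 0.585 for T cells, 3.89e-04 to 0.585 for dendritic cells and 4.03e-07 to 0.637 for the hepatocyte lineage. In that order the lists passed in 4, 3 and 2 of these, 1 each being camera with a preset correlation.

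What lenvatinib added to anti-PD1 was read from 5 combination and 5 anti-PD1 tumours, and here 10 of the 39 lists passed, 8 of them higher in the combination. T cell genes rose by 1.53 ± 0.34, a ratio of 2.9 (fry adjusted p = 0.0121), and 4 of 5 combination tumours lay above every anti-PD1 tumour. The mean T cell scores were 0.18 in placebo, -0.73 in anti-PD1 and 0.80 in the combination. Part of the difference is thus that anti-PD1 tumours lay below placebo. All 13 members lay above 0 and 12 were past the threshold adjusted over the list alone, against 0 over all genes. Cd2 stood at 1.77 ± 0.32, Lat, an adaptor of the T cell receptor, at 1.76 ± 0.34, Sit1 at 2.02 ± 0.40 and Cd247 at 1.16 ± 0.25. Cytotoxic lymphocyte genes rose by 1.17 ± 0.33 (adjusted p = 0.0199), with 12 of 18 past the threshold adjusted over the list alone, and again 4 of 5 combination tumours lay above every anti-PD1 tumour. Cd8b1 stood at 2.48 ± 0.54, Cst7 at 1.77 ± 0.42 and Nkg7, a granule protein of killer cells, at 1.77 ± 0.46. NK cell genes rose by 0.95 ± 0.32 (adjusted p = 0.0472), with 5 of 11 past the threshold adjusted over the list alone and 4 of 5 combination tumours above every anti-PD1 tumour. That list did not pass in camera with an estimated correlation (adjusted p = 0.0764, and 2.12e-07 to 0.196 over its 20 alternatives). Eomes, a transcription factor of killer cells, stood at 1.02 ± 0.32 and the receptors Klrd1 and Klrc1 at 1.86 ± 0.61 and 1.44 ± 0.48. Regulatory T cell genes rose by 0.74 ± 0.26 (adjusted p = 0.0474), with 5 of 11 past the threshold adjusted over the list alone and 4 of 5 combination tumours above every anti-PD1 tumour. That list too did not pass in camera with an estimated correlation (adjusted p = 0.0867, and 3.19e-05 to 0.155 over its 20 alternatives). The members with the smallest p-values were Tnfrsf4 at 1.45 ± 0.41, Tnfrsf18 at 0.87 ± 0.25 and Icos at 2.00 ± 0.59, costimulatory receptors that activated conventional T cells carry too, and Cd4 at 0.97 ± 0.33. Foxp3, on the fixed list, was not matched to a named probe set. The rise is thus not told apart from one of T cells in general.

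**Figure D2:**
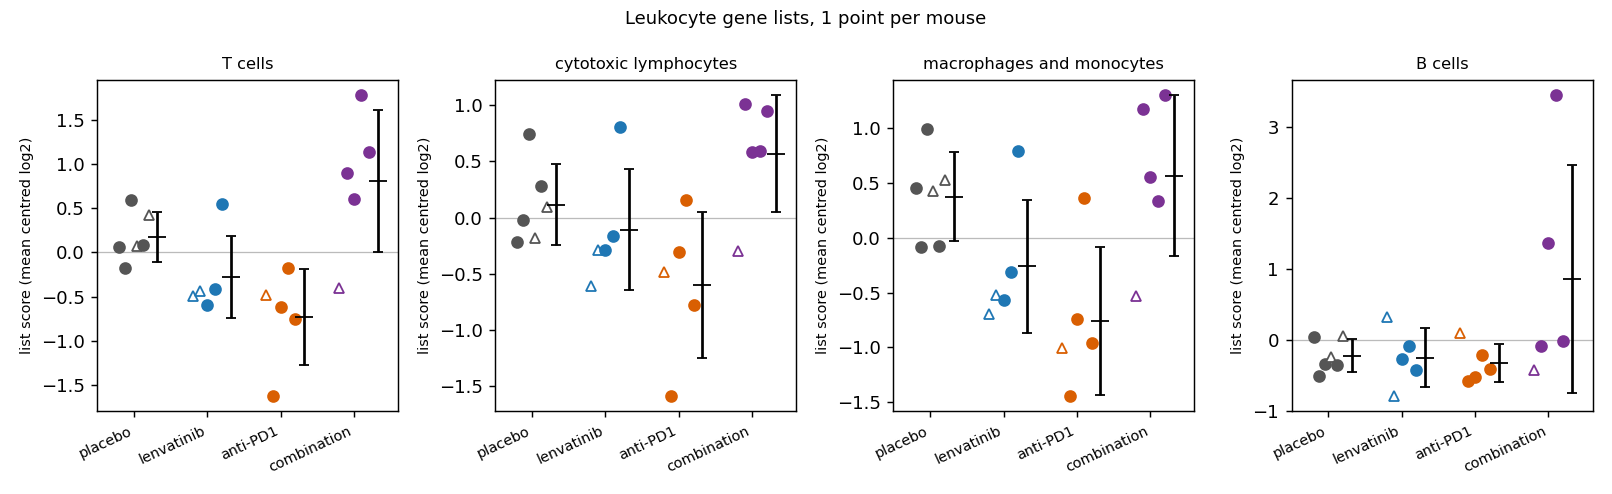
Scores (mean centred log2) of the T cell, cytotoxic lymphocyte, macrophage and B cell lists, 1 point per mouse, by arm, with open triangles for the 6 arrays with bright hybridization controls and black bars for the arm mean ± SD (n = 6, 5, 5 and 5). The T cell scores average -0.73 in anti-PD1 and 0.80 in the combination, where mouse 1 lies at -0.41, and the B cell scores of combination mice 3 and 4 are 1.36 and 3.45.

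Myeloid and antigen-presenting cell genes were higher in the combination than in anti-PD1 as well. Macrophage and monocyte genes rose by 1.32 ± 0.38, a ratio of 2.51 (fry adjusted p = 0.0199), with 15 of 16 past the threshold adjusted over the list alone and 3 of 5 combination tumours above every anti-PD1 tumour. The list did not pass in camera with an estimated correlation (adjusted p = 0.0501, and 1.93e-19 to 0.155 over its 20 alternatives). Mean macrophage scores were 0.37 ± 0.41 in placebo, -0.76 ± 0.68 in anti-PD1 and 0.57 ± 0.74 in the combination (SD). Most of the difference is thus that anti-PD1 tumours lay below placebo. Means of NK cells (0.16, -0.54 and 0.42) and MHC class II genes (0.11, -0.51 and 0.47) had the same order. Cd86, a costimulatory ligand, stood at 1.58 ± 0.39, Tyrobp at 1.72 ± 0.42, the integrin Itgam at 1.49 ± 0.41 and the Fc receptor chain Fcer1g at 1.59 ± 0.44. Dendritic cell genes rose by 0.68 ± 0.18 (adjusted p = 0.0199), with 6 of 13 past the threshold adjusted over the list alone and 4 of 5 combination tumours above every anti-PD1 tumour. Batf3, which conventional type 1 cells need, stood at 0.95 ± 0.26, Itgax at 2.15 ± 0.62, Flt3 at 0.89 ± 0.28 and Xcr1 at 1.01 ± 0.33. MHC class II genes rose by 0.98 ± 0.30 (adjusted p = 0.0426), with 9 of 11 past the threshold adjusted over the list alone and 4 of 5 combination tumours above every anti-PD1 tumour. This list did not pass in camera with an estimated correlation (adjusted p = 0.066, and 4.09e-10 to 0.183 over its 20 alternatives). H2-Aa stood at 0.98 ± 0.27, H2-DMa at 1.05 ± 0.34 and H2-Ob at 1.78 ± 0.58 (1.10 without combination mouse 4). Plasma cell genes rose by 1.00 ± 0.29 (adjusted p = 0.0199), with 1 of 8 past the threshold adjusted over the list alone and 4 of 5 combination tumours above every anti-PD1 tumour. Mzb1, a chaperone of antibody assembly, stood at 2.30 ± 0.58 and Jchain, which joins antibody polymers, at 2.64 ± 1.06.

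Schwann cell and cholesterol synthesis genes were the 2 lists lower in the combination than in anti-PD1. Schwann cell genes, of the glia of peripheral nerves, stood at -0.60 ± 0.17 (fry adjusted p = 0.0199), with 0 of 6 past the threshold adjusted over the list alone and 4 of 5 combination tumours below every anti-PD1 tumour. Mbp stood at -0.79 ± 0.28, Sox10, a transcription factor of these cells, at -0.98 ± 0.47 and Mal at -0.69 ± 0.38, and Cdh19, with a mean signal below the median of the negative controls in every arm, at -0.94 ± 0.41. Cholesterol synthesis genes stood at -0.47 ± 0.18 (adjusted p = 0.0456), with 3 of 15 past the threshold adjusted over the list alone and 5 of 5 combination tumours below the anti-PD1 mean. The list did not pass in camera with an estimated correlation (adjusted p = 0.066, and 2.66e-04 to 0.181 over its 20 alternatives). The desaturase Sc5d stood at -1.07 ± 0.26, the squalene synthase Fdft1 at -0.88 ± 0.28, Hmgcs1 at -1.07 ± 0.37 and Nsdhl at -0.53 ± 0.26. Lists that did not pass include suppressive myeloid genes at 1.10 ± 0.39 (adjusted p = 0.0668), checkpoint receptors and ligands at 0.84 ± 0.34 (adjusted p = 0.0866) and B cells at 1.18 ± 0.52 (adjusted p = 0.106), or 0.53 without combination mouse 4. Pdcd1 stood at 1.37 ± 0.53 and Cd274 at 0.96 ± 0.41. Tip cell genes, which depend on VEGF, stood at -0.33 ± 0.17, with the vascular adhesion gene Mcam at -1.50 ± 0.36 and Cxcr4, a chemokine receptor that leukocytes express too, at 1.77 ± 0.41. Endothelial genes stood at -0.37 ± 0.35, with Nos3 at -0.83 ± 0.24. Without anti-PD1 mouse 2 the endothelial list stood at -0.09, Cdh19 at -0.40, Sox10 at -0.64, Nsdhl at -0.27 and Cd274 at 0.54. Without combination mouse 1 the endothelial list stood at -0.20.

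**Figure D3:**
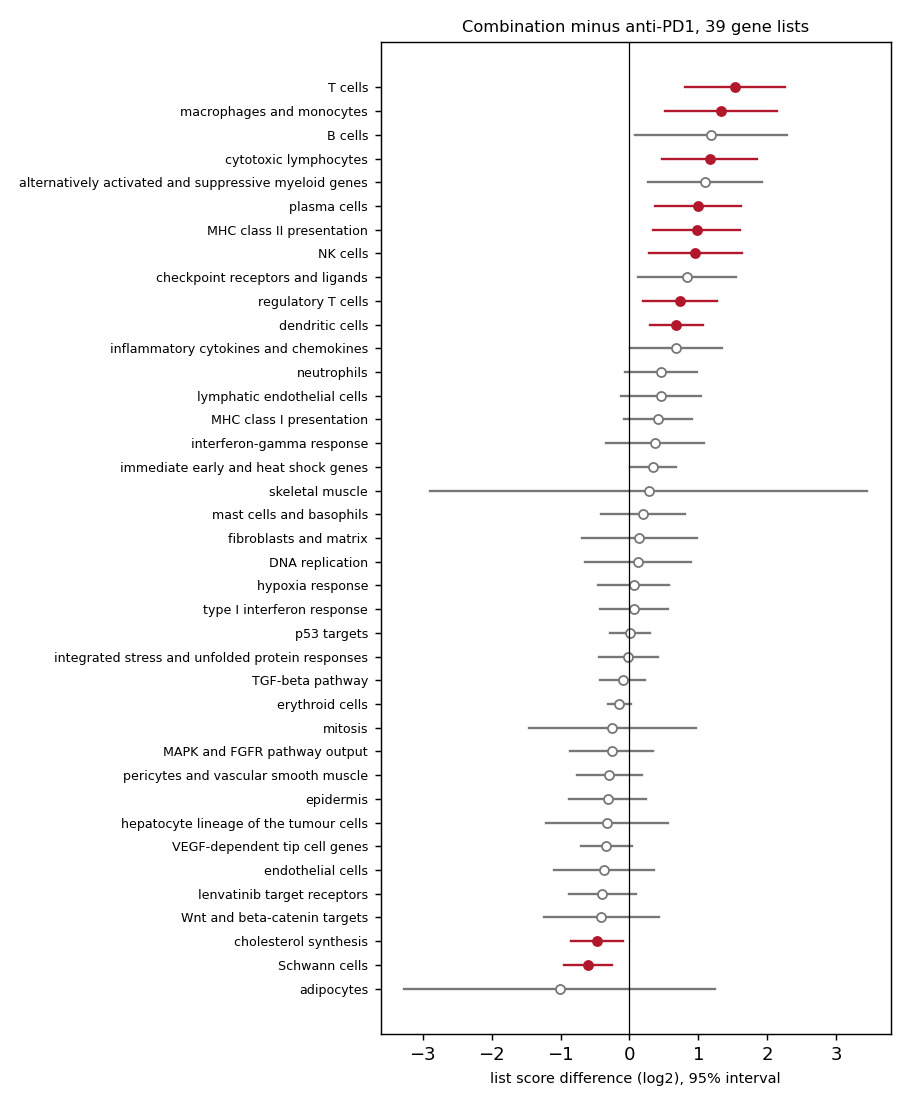
Difference in list score (log2) between combination and anti-PD1 tumours (n = 5 and 5) for each of the 39 gene lists, with its 95% interval as a line. Filled red points are the 10 lists with a fry adjusted p under 0.05, of which T cells lie highest at 1.53 and Schwann cells lowest at -0.60.

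No single probe set passed for the combination against anti-PD1 in limma, with 0 of 22206 and a smallest adjusted p of 0.123. At an unadjusted p under 0.05, 1078 were higher and 619 lower, against 1110 by chance. The genes with the smallest p-values besides Cd2 were Rac2, a GTPase of blood cells, at 2.02 ± 0.37 and AB124611 at 1.99 ± 0.38. On the lower side were Reep6 at -1.87 ± 0.39, Slc44a3 at -1.57 ± 0.34 and the junction protein Afdn at -0.98 ± 0.22. Anti-PD1 mouse 2, with the highest adipocyte score and a muscle score of 3.04, had the lowest T cell score of the 21 tumours at -1.63. Combination mouse 1, with a bright-control array, had the lowest T cell score of its arm. Array weights called 374 probe sets higher and 130 lower. Leaving out combination mouse 1 gave 308 higher and 30 lower, leaving out anti-PD1 mouse 4 gave 85 higher and 2 lower, and leaving out the 6 bright-control arrays gave 143 higher and 90 lower. The 10 lists became 15 without combination mouse 1. They became 1 without anti-PD1 mouse 2 or without combination mouse 5, 4 without combination mouse 2 or 4, and 6 without anti-PD1 mouse 5 or combination mouse 3. The T cell call held in all 10 omissions of 1 mouse, and the dendritic cell call in all but those of anti-PD1 mouse 2 and combination mouse 5. Without either of these mice the cytotoxic, macrophage, plasma cell and Schwann cell calls were lost as well. The cytotoxic and macrophage calls were also lost without combination mouse 2, the plasma and Schwann cell calls without combination mouse 4, and the Schwann cell call without anti-PD1 mouse 1, with array weights and without the 6 arrays. Among the omissions of 1 mouse, NK and regulatory T cell calls held only without anti-PD1 mouse 4 or combination mouse 1. The MHC class II call held without those or anti-PD1 mouse 3, and the cholesterol call without those or anti-PD1 mouse 1. In camera with an estimated correlation the T, cytotoxic, dendritic, plasma and Schwann cell lists passed. An exact two-sided permutation test of the scores, which cannot go below 0.00794 here, gave p = 0.0159 for T cells (n = 5 and 5). After adjustment 0 of 39 lists passed it (adjusted p = 0.124 for T cells, 4.94e-23 to 0.124 over its 20 alternatives). With 5 mice against 5 it can pass only if several lists lie at or near the smallest possible p, so this decides little. Without combination mice 3 and 4, left out after their B cell scores were seen, fry called 0 lists (smallest adjusted p = 0.0859). The differences then were 1.27 ± 0.37 for T cells, 1.41 ± 0.47 for macrophages, 0.46 ± 0.18 for dendritic cells and 0.63 ± 0.31 for MHC class II, with 3 mice left against 5.

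The single agents were compared directly in 5 lenvatinib and 5 anti-PD1 tumours. No list passed. The endothelial list stood at -0.62 ± 0.35 (fry adjusted p = 0.487), 22 of 23 below 0, with Nos3 at -0.96 ± 0.24, Cldn5 at -2.01 ± 0.74 and the VEGF receptor Kdr at -1.24 ± 0.64. Tip cell genes stood at -0.33 ± 0.17 (adjusted p = 0.487), with Mcam at -1.55 ± 0.36 and the laminin chain Lama4 at -1.18 ± 0.40. Anti-PD1 mouse 2, whose muscle and adipocyte scores were high, had the highest endothelial score of the 21 tumours, 1.45, and without it the list stood at -0.34 and Kdr at -0.76. Interferon-gamma response genes stood at 0.68 ± 0.34 (adjusted p = 0.487), 19 of 21 above 0, with the GTPases Gbp3 at 0.88 ± 0.34 and Irgm1 at 0.96 ± 0.39. Cd274 stood at 1.20 ± 0.41. Without anti-PD1 mouse 2 Irgm1 stood at 0.60 and Cd274 at 0.79. T cell genes stood at 0.45 ± 0.34 (0.23 without anti-PD1 mouse 2, 0.25 without lenvatinib mouse 5) and adipocyte genes at -2.09 ± 1.07. The morphogen gene Bmp3 at -1.01 ± 0.24, Hirip3 at 0.90 ± 0.24 and Tmem71 at 0.90 ± 0.25 were among the genes with the smallest p-values. With limma 0 of 22206 probe sets passed (smallest adjusted p = 0.955), and 0 passed with array weights. At an unadjusted p under 0.05, 344 were higher and 675 lower, against 1110 by chance. Of the 39 lists, fry called 0, with 2 at an unadjusted p under 0.05, camera with a preset correlation called 21, and camera with an estimated correlation and an exact permutation test called 0.

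Whether lenvatinib acted differently in the presence of anti-PD1 was tested as an interaction over all 21 tumours. It is the difference between combination and anti-PD1 minus that between lenvatinib and placebo. The interaction was above 0 for 4 lists of immune cells and below 0 for cholesterol synthesis. For T cell genes lenvatinib alone stood at -0.46 ± 0.33 from placebo, and the interaction was 1.99 ± 0.48 (fry adjusted p = 0.0222), with 12 of 13 past the threshold adjusted over the list alone. In camera with an estimated correlation it did not pass (adjusted p = 0.0878, and 1.33e-18 to 0.0878 over its 30 alternatives). Cd2 stood at 2.35 ± 0.44 and Lat at 2.13 ± 0.46. For macrophages and monocytes it was 1.96 ± 0.53 (adjusted p = 0.033), where lenvatinib alone had stood at -0.63 ± 0.37. All 16 members were past the threshold adjusted over the list alone, including Tyrobp at 2.42 ± 0.59, Ms4a7 at 2.41 ± 0.60 and the complement gene C1qb at 2.19 ± 0.56. The list had adjusted p = 0.0878 in camera with an estimated correlation (4.29e-19 to 0.105 over its 30 alternatives). For dendritic cells the interaction was 0.85 ± 0.25 (fry adjusted p = 0.0413), with 3 of 13 past the threshold adjusted over the list alone. Camera with an estimated correlation gave adjusted p = 0.0878 (2.79e-05 to 0.114 over the list's 30 alternatives). Batf3 stood at 1.25 ± 0.37 and Flt3 at 1.27 ± 0.38. For cytotoxic lymphocytes the interaction was 1.39 ± 0.45 (fry adjusted p = 0.0485), with 9 of 18 past the threshold adjusted over the list alone. Camera with an estimated correlation gave adjusted p = 0.142 (5.46e-12 to 0.142 over the list's 30 alternatives). Cd8b1 stood at 3.13 ± 0.75 and the granule protease Ctsw at 1.78 ± 0.46. For cholesterol synthesis the interaction was -0.75 ± 0.25 (fry adjusted p = 0.0445), with 0 of 15 past the threshold adjusted over the list alone. Camera with an estimated correlation gave adjusted p = 0.0878 (1.06e-04 to 0.105 over the list's 30 alternatives). Sc5d stood at -1.06 ± 0.37 and Fdps, which makes farnesyl pyrophosphate, at -1.33 ± 0.62.

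Other lists departed from additivity without passing, such as MHC class II at 1.18 ± 0.42 (adjusted p = 0.0926) and suppressive myeloid genes at 1.51 ± 0.54, with Trem2 at 3.62 ± 0.84. Hepatocyte lineage genes stood at -1.21 ± 0.58 and mitosis genes at -1.33 ± 0.80. Fibroblast and matrix scores averaged 0.37 in placebo, -0.54 in lenvatinib, -0.02 in anti-PD1 and 0.12 in the combination, so lenvatinib went with lower scores only without anti-PD1. Whether the share of tumour cells lies behind the interaction was not tested. Single genes with the smallest p-values were Cd7, a receptor of T and NK cells, at 2.69 ± 0.52, AB124611 at 2.65 ± 0.52, Plekha6 at -1.79 ± 0.35, Wasf1 at -1.45 ± 0.29 and the transcriptional co-activator Yap1 at -1.61 ± 0.36. Clec4d stood at 4.10 ± 0.90 and Pdcd1 at 1.92 ± 0.73. In limma 0 of 22206 probe sets passed (smallest adjusted p = 0.151), and 1266 lay above and 736 below 0 at an unadjusted p under 0.05, against 1110 by chance. Array weights called 772 above and 919 below. Without combination mouse 1 there were 285 above and 35 below, without lenvatinib mouse 5 there were 79 above and 2 below, and without anti-PD1 mouse 4 there were 7 above. The 5 lists became 13, 10 and 9 in these omissions. They became 3 without placebo mouse 1 or 4, and 2 without placebo mouse 5 or combination mouse 2 or 4. Only 1 was left without placebo mouse 3 or 6, lenvatinib mouse 4, anti-PD1 mouse 2, 3 or 5, or combination mouse 3. With 0 lists past the threshold in fry were the omissions of lenvatinib mouse 1, 2 or 3 and of combination mouse 5. So were those of the 6 bright-control arrays (smallest adjusted p = 0.0556) and of combination mice 3 and 4 (smallest adjusted p = 0.0661). In these 2 fits the T cell interaction was 2.20 ± 0.54 and 1.73 ± 0.48, and that of macrophages 1.89 ± 0.65 and 2.04 ± 0.61.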

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

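The tests of array quality, tumour-cell share and lymph node tissue on the difference between combination and anti-PD1, and those on the 6 arrays, were chosen after the results were seen. Mice far from the rest of their arm were sought in all 39 lists and in the 132 genes named, and chance alone flags about 1 in 20 arms tested. Of 156 tests of list scores 11 were flagged, and of 528 tests of genes 34.

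Lenvatinib mouse 5 lay above the rest of its arm in T cells at 0.54, NK cells at 0.785 and macrophages at 0.80. Its genes far above the other lenvatinib mice were C1qb (10.0), H2-Aa (11.1), Itgam (9.37), Ms4a7 (11.1), Nkg7 (9.35) and Trem2 (8.92). Combination mouse 1 lay below the rest of its arm in checkpoint receptors at -0.46 and NK cells at -0.69. Its genes far below were Cd3g (7.72), Icos (5.20), Jchain (6.13), Klrd1 (4.82), Lama4 (5.70), Nos2 (6.44) and Pmepa1 (7.27), with Plekha6 (5.49) far above. Anti-PD1 mouse 2 lay below the others of its arm in inflammatory cytokines at -1.53 and above them in skeletal muscle at 3.04. It had Cd3d (4.02) far below, and Cdh19 (5.94), Fdft1 (9.29) and Reep6 (8.25) far above. Combination mouse 2 had a muscle score of 4.52, and lenvatinib mouse 2 an epidermis score of 1.10. Lymphatic endothelial scores were -0.39 in placebo mouse 4, below its arm, and 1.44 in combination mouse 4, above it, where Chst4 (5.14) and Marco (7.58) were far above too. Anti-PD1 mouse 4 lay far above its arm in Csf1r (9.67), Cst7 (8.55) and Rassf5 (6.81). Anti-PD1 mouse 1 lay above it in Flt3 (4.01) and below it in Mecom (5.74). Single mice far from their arm were placebo mouse 4 in Afdn (5.63) and Wasf1 (3.18), both low, placebo mouse 3 in Ctsw (6.94) and Xcr1 (6.06), and placebo mouse 1 in Mbp (5.92) and Nsdhl (8.35), all high. Lenvatinib mouse 1 was high in Pgk1 (9.01) and Siglech (5.09), and combination mouse 5 low in Fdft1 (6.57).

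The effect of lenvatinib differed by the interaction test between mice with and without anti-PD1 for 5 lists. The differences were 1.99 for T cells, 1.39 for cytotoxic lymphocytes, 1.96 for macrophages and monocytes, 0.85 for dendritic cells and -0.75 for cholesterol synthesis. None of the 5 passed in camera with an estimated correlation (adjusted p = 0.0878 to 0.142). All 5 fry calls were lost without the 6 bright-control arrays and without combination mice 3 and 4. The differences in these last fits were 2.20 and 1.73 for T cells, 1.49 and 1.38 for cytotoxic lymphocytes, 1.89 and 2.04 for macrophages, 0.92 and 0.63 for dendritic cells, and -0.82 and -0.84 for cholesterol synthesis. Among 100 splits of the mice, the real one included, 2 gave as many lists, with 5 in the real split and 9 in the highest other. Such a count from fry was thus uncommon among splits, but chance was not excluded, since the counts tested were not adjusted for one another. For the combination against anti-PD1 3 of 100 gave as many lists, with 10 in the real split and 13 in the highest other, and the same limit holds there.

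For the lists of the other 5 comparisons the splits decide nothing, since a real count of 0 is met by all 100 of 100 splits. The highest others were 2 (lenvatinib against placebo), 13 (anti-PD1 against placebo), 3 (combination against placebo), 14 (combination against lenvatinib) and 3 (lenvatinib against anti-PD1). Chance was not excluded for the counts of probe sets either. Those at an unadjusted p under 0.05 were as many in 20 splits for lenvatinib against placebo (1548, highest other 3852) and in 55 for anti-PD1 against placebo (903, 4891). They were as many in 48 for the combination against placebo (512, 2465), in 18 for it against lenvatinib (1421, 4765) and in 22 for it against anti-PD1 (1697, 3557). For lenvatinib against anti-PD1 44 splits (1019, 5486) and for the interaction 19 (2002, 6158) gave as many. Single splits had up to 2014, 1097, 568 and 293 probe sets past the adjusted threshold, for anti-PD1 against placebo, the combination against lenvatinib, the same against anti-PD1 and the interaction. Shuffled residuals gave up to 1689, so such counts arise without the arms, and whether a structure of the samples lies behind them was not tested.

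The mean score of all 11 fixed lists of leukocyte types, 7 of which passed in this comparison, was higher by 0.94 in combination than in anti-PD1 tumours (n = 5 and 5). The 11 were pooled after the results were seen, so the p-values here are no independent test of the difference. Array quality was argued against as the whole cause, since without the 6 bright-control arrays the difference was 1.17 (exact p = 0.0286, the smallest possible, n = 4 and 4). A lower share of tumour cells, filled by leukocytes and stroma alike, would raise both. The leukocyte score minus that of endothelial, pericyte and fibroblast lists was higher by 1.11 (exact p = 0.00794), and stroma stood at -0.17 (exact p = 0.635). Without anti-PD1 mouse 2 these values were 0.74 (exact p = 0.00794) and 0.06. Hepatocyte lineage scores, of the tumour cells, averaged -0.26 ± 0.75 in the combination and 0.07 ± 0.75 in anti-PD1 (SD, n = 5 and 5). The values argue against leukocytes and stroma rising alike, but a lower tumour-cell share filled mainly by leukocytes was not excluded. Lymph node tissue in combination mice 3 and 4 cannot be told apart from the treatment as part of the cause, since without them the difference was 0.78 with 3 mice left against 5 (exact p = 0.107), and the addition of lenvatinib stays open as the biological explanation.

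The 6 arrays with bright hybridization controls also had higher poly-A spike-ins, which are added to the sample before labelling. Poorer labelling was argued against, since the poly-A signals were higher by 1.51 (6.46 against 4.95, permutation p = 5.53e-05). Their rise exceeded that of the hybridization controls by 0.32, as less or more degraded sample RNA relative to the spike-ins would give. The treatment arm was argued against, since all 4 arms held both kinds of array. No other biological explanation was tested.

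B cell genes were highest in combination mice 3 and 4. In an added list of 9 genes of lymph node stroma and resident macrophages, none of them in the B cell list, these mice had scores of 0.55 and 2.08, and the lower lay 0.48 above the highest of the other 19 mice. In mouse 4, 8 of the 9 genes lay above all other 19 mice, but in mouse 3 the score rested mostly on Cd209b and Ccl19, 1.62 and 0.57 above them, with Fut7, Chst4, Siglec1 and Madcam1 within the others' range. Lymph node tissue taken with the tumour is thus a candidate explanation with weaker evidence in mouse 3, and lymphoid structures formed inside the tumour, which carry some of the same genes, were not tested and stay open. Mammary epithelium was argued against, since in its 8 measured genes the lower of the 2 mice lay at -1.13 from the highest of the others. That evidence is limited, as Csn1s1 had at most 3.25 in any mouse, below the negative-control median of 4.10. Fat of the mammary gland is not covered by these genes.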

How the results depend on the processing

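Array weights for lists, the hybridization control covariate, and leaving out 6 arrays or combination mice 3 and 4 were chosen after the data were seen. No call changed direction. Array weights gave 707, 504 and 1691 probe sets for the combination against lenvatinib, the combination against anti-PD1 and the interaction, where the fit without weights gave 0, and 3 lists for the first and 18 for the last. Cyclic loess gave 1 list for anti-PD1 against placebo. Camera with a preset correlation gave 11, 24 and 20 lists for lenvatinib, anti-PD1 and combination against placebo, 24 and 26 for the combination against lenvatinib and anti-PD1, 21 for lenvatinib against anti-PD1 and 23 for the interaction. With an estimated correlation camera gave 5 for the combination against anti-PD1 and 0 for the interaction. The exact permutation test, which can hardly pass with 5 mice against 5, gave 0 for the combination against anti-PD1. The control covariate gave 8 lists for the interaction. Without the 6 arrays there were 233 probe sets for the combination against anti-PD1, 202 of them also called with array weights, and 0 lists for the interaction. Array weights gave those 6 arrays low weights of 0.18 to 0.64, so the shared calls are no independent agreement. Without combination mice 3 and 4 there were 0 lists for the combination against anti-PD1 and 0 for the interaction. With 1 mouse left out, probe sets ranged from 0 to 338 for the combination against anti-PD1, 0 to 320 for the interaction, 0 to 1 for the combination against lenvatinib and 0 to 0 elsewhere. Lists ranged from 1 to 15, 0 to 13 and 0 to 2 in these, 0 to 1 for anti-PD1 against placebo and 0 to 0 elsewhere. The cause was not tested, beyond the smaller number of mice. Mouse numbers as a replicate block gave 0 lists for the interaction (smallest adjusted p = 0.0522) and changed no other count by over 1.5 times. The numbers do not pair the mice: 15 of 30 correlations exceeded 0.1 (-0.63 to 0.56), and 3 of 20 mice matched their own number best. Over all alternatives, 203 values of single lists and 234 of single genes newly passed the threshold, and 155 values of lists fell short of it. Of the 203, 134 came from camera with a preset correlation. Direction turned in 270 values of lists and 116 of genes, 0 of them past the threshold in either fit, 23 and 18 of them by more than the standard error. Of these, 14 and 7 turned without the 6 arrays, such as mitosis in combination against placebo (0.27 ± 0.55 to -0.32), and 5 and 2 with array weights, such as adipocytes in combination against anti-PD1 (-1.01 ± 1.07 to 0.49). Signal over background limits genes near the negative-control median of 4.10, such as Cdh19, below it in every arm, and Flt3, Pzp, Adam3, Wasf1, Hirip3, Eomes, Klrc1, B3gnt5, Vnn1 and Ltf, below it in some arms.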

Other observations

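Further groups of genes stood apart between arms without passing the test over lists. Inflammatory cytokine and chemokine genes stood at 0.68 ± 0.32 in combination against anti-PD1 (fry adjusted p = 0.137), and at 0.40 without anti-PD1 mouse 2. In that list 5 of 5 combination tumours lay above every anti-PD1 tumour, though combination mouse 4 (-0.040) and anti-PD1 mouse 3 (-0.043) nearly tied. Tnf, the tumour necrosis factor gene, stood at 1.12 ± 0.31 and Nos2, the inducible nitric oxide synthase of activated macrophages, at 2.46 ± 0.78. MHC class I genes stood at 0.42 ± 0.23 (adjusted p = 0.156), with the nonclassical molecules H2-T23 at 0.80 ± 0.30 and H2-M3 at 0.98 ± 0.42. Without anti-PD1 mouse 1 that list stood at 0.27 and H2-M3 at 0.63. Type I interferon genes differed little in that comparison, at 0.06 ± 0.23 with a 95% interval of -0.43 to 0.56. In lenvatinib against placebo, DNA replication genes stood at 0.59 ± 0.35 (adjusted p = 0.447), with the licensing factor Cdt1 at 0.98 ± 0.42 and the helicase subunit Mcm5 at 0.92 ± 0.40. Placebo mice 1, 4 and 6 were the lowest of their arm in that list, at -0.89, -0.82 and -0.74. Integrated stress genes stood at 0.23 ± 0.19 (adjusted p = 0.567), 12 of 17 above 0, and the members with the smallest p-values, the serine synthesis genes Phgdh and Psat1, at 1.21 ± 0.53 and 1.01 ± 0.55. Without placebo mouse 6 that list stood at 0.11 and Psat1 at 0.64. Of the TGF-beta genes, at -0.03 ± 0.15 as a list, Tgfb3 stood at -0.76 ± 0.36 and the feedback inhibitor Pmepa1 at -0.86 ± 0.42. Pdpn, a membrane protein of lymphatic endothelium and fibroblasts, stood at -1.10 ± 0.48 in lenvatinib and -1.19 ± 0.48 in anti-PD1 against placebo, and its interaction was 2.15 ± 0.69. Neutrophil genes stood at -0.43 ± 0.24 in lenvatinib against placebo, with Ltf, an iron-binding granule protein, at -1.40 ± 0.54.

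Genes of lymph node stroma and resident macrophages were brightest in combination mouse 4, in 8 of 9 measured, and less uniformly high in mouse 3. Cd209b, a lectin of sinus macrophages, had signals of 5.81 and 8.24 in mice 3 and 4 and at most 4.20 in the other 19 mice. Ccl19, a chemokine that draws T cells, had 7.72 and 9.44 against at most 7.15. Fcamr had 5.67 and 7.13 against at most 5.58, Marco 5.63 and 7.58 against 5.62, and Coch 4.78 and 5.81 against 4.76. In mouse 3, Siglec1 (6.01 and 7.17, others at most 6.29), Chst4 (3.20 and 5.14, others at most 3.40) and Fut7 (5.61 and 6.81, others at most 6.49) lay within the range of the others. Madcam1, an adhesion molecule of mucosal and node venules, had 4.89 and 5.73, within that range in both mice, as the others reached 7.31.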
